A study of Homo sapiens with 6 samples.

How the data were processed

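RNA was measured in human bone marrow mesenchymal stem cells of passage under 5, grown in medium with 16.5% serum, in 6 libraries: 2 controls, 2 with MoS2 1:1 and 2 with MoS2 1:6. The authors deposited a table of RPKM values per gene and library. Their processing notes name bcl2fastq for demultiplexing and STAR for alignment to hg38, without versions. The annotation, the definition of gene length and the filter on genes are not stated. All listed genes have an RPKM of at least 1 in at least 2 libraries, so a filter at that level removed no gene.

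Each deposited value is a whole number of reads times a factor per gene and a factor per library. Lengths and totals were searched for among 1453 genes with a single annotated coding length, of which 1309 gave the same library totals and 25 the next most common. With these totals 100% of values came out whole within 1e-04 reads. Of 11011 symbols with an annotated coding length, 7610 (69.1%) had a recovered length equal to it, and 83.5% of recovered lengths were multiples of 3. For 66 genes the reads were multiplied by a common factor. The listed genes hold 99.6% to 99.7% of the recovered totals. The search was tested on simulated data, where 98.9% of 800 genes came out exact. Recovered reads were used for depth, composition and alternatives. The main tests used the deposited RPKM.

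Genes were tested with limma 3.58.1 in R 4.3.3, on log2(RPKM + 1), with 1 mean per group over all 6 libraries, empirical Bayes variances with a trend, and Benjamini-Hochberg adjusted p under 0.05. The fit has 3 residual degrees of freedom and 5.56 prior ones. The 3 comparisons are each nanoparticle group against control and MoS2 1:6 against MoS2 1:1. Fold changes of single genes are ratios of mean RPKM, and log2 fold changes are those of the model. Before the data were examined 57 gene lists were written, and the 52 with at least 5 members in the table were tested with camera at a preset correlation between genes of 0.01. Camera was also run with an estimated correlation, and fry with directional and mixed p-values. With an estimated correlation camera takes the 3 residual degrees of freedom of the fit, so few lists can pass. For chondrogenic genes with MoS2 1:1 the estimated correlation was -0.024, below the preset. Their unadjusted camera p still rose from 3.62e-12 to 0.00545. A call lost in that test therefore does not show that correlation between genes made the call. Tested on simulated reads at these depths, limma found 71%, 66% and 65% of genes changed 2-fold in the comparisons as listed, and 100%, 99% and 100% of those changed 4-fold, with 6, 10 and 13 false calls. Camera found the raised list in each of them and called 0 of 40 unchanged lists. The simulated genes were independent, with a dispersion of 0.02 in all groups. In the real data the estimated correlation was as high as 0.90, for complex IV, and control replicates spread more than the others. The simulated shares therefore do not give the error rates of the real tests.

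Genes named in the text follow a rule written before the data were examined. They are the 10 highest and 10 lowest fold changes per comparison among called genes whose libraries do not overlap, up to 4 called genes of a shifted list or 2 of another, and PPARGC1A, SIRT1, SIRT3, NRF1, TFAM, ESRRA, NQO1, HMOX1, CAT and SOD2. The text names part of these. SDC1 and CRYAB were chosen after their values were seen.

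Alternatives were other pseudocounts (0.1 and 0.01), a minimum RPKM of 5 or none, median-of-ratios scaling, quantile normalization, RPKM rescaled to the same sum, only the 4 libraries compared, no variance trend, robust variances, a replicate block, each library left out, and a 2-fold minimum. Chosen after seeing the data were voom on recovered reads, voom with median-of-ratios totals, totals without the 20 most abundant genes, median-of-ratios scaling with a replicate block, and separate controls for the correlation of the responses. Coordinates come from the RefSeq annotation of GRCh38.p14, matched by gene identifier for 11124 genes. Coding lengths are those recovered from the RPKM values, and the annotated coding lengths they were compared with are from GENCODE. GC content is that of the longest protein-coding GENCODE transcript of a gene, found for 11096 genes. Lists were compared with 10000 random lists matched on coding length, GC content and level in 5 classes each. Genes were drawn independently within classes. The ranges therefore leave out correlation between genes, which can make them too narrow, and any trend within a class. The list of respiratory subunits was first matched on part of its members, before renamed ATP synthase genes were joined, and then on all 81, with the prediction unchanged and the same percentile. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.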

Results

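Human mesenchymal stem cells (hMSCs) are stromal cells, here from bone marrow, that can form bone, cartilage and fat in culture. They were grown alone or with nanoparticles of molybdenum disulfide (MoS2), a layered solid of molybdenum and sulfur. Particles labelled 1:1 had few atomic vacancies, which are lattice sites that lack an atom, and particles labelled 1:6 had many. Both were given at 25 µg/mL, and total RNA was taken after 7 days. The 3 groups held 2 libraries each. Whole reads recovered from the deposited RPKM (reads per kilobase and per 1e6 reads) gave library totals of 13595204 and 13408591 in the controls, 10993009 and 13806395 in MoS2 1:1, and 9948004 and 9418395 in MoS2 1:6. The median gene held 167 to 275 reads in a library. The labels do not say whether the libraries of a group came from separate cultures or donors. The limma p-values of genes therefore measure only the spread between these libraries, which may be technical. The preset camera p-values set a list against the spread of the other genes. They do not measure the spread between libraries, cultures or donors.

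The nanoparticle libraries stood apart from the controls on the first principal component, which held 64.1% of the variance, and the second placed both MoS2 1:1 libraries apart from the rest. Replicates differed with an SD of log2 differences of 0.40 in the controls, 0.21 in MoS2 1:1 and 0.30 in MoS2 1:6. In the control pair this difference followed the GC content and coding length of the genes. Together with the mean level of the genes, these held 42.4% of its variance, against 2.71% and 2.92% in the nanoparticle pairs. FN1 (fibronectin), COL1A1, COL1A2 (type I collagen) and SERPINE2, a secreted protease inhibitor, together took 19.1% and 21.1% of the reads in the controls and 9.98% to 10.5% in the nanoparticle libraries. FN1 alone took 9.79% and 10.5% of control reads, 6.44% and 6.48% in MoS2 1:1, and 5.30% and 4.88% in MoS2 1:6. On the deposited RPKM the median log2 fold change of all genes was 0.30 for MoS2 1:1 against control, 0.18 for MoS2 1:6 against control and -0.11 for MoS2 1:6 against MoS2 1:1. Medians of gene lists are therefore given less this shift, as relative medians, while the values of single genes are on the deposited scale.

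The comparison of MoS2 1:1 with control asks what 7 days with particles of few vacancies did to RNA levels. Of 29 NRF2 targets 20 rose, as did all 77 cytosolic ribosomal proteins and 33 of 37 subunits of respiratory complex I, while 29 of 40 collagens and matrix genes, 6 of 10 smooth muscle markers and 7 of 9 chondrogenic genes fell. None of these list calls held with an estimated correlation (adjusted p = 0.115 to 0.501). That test has 3 degrees of freedom and little power, so here and below its losses do not show that correlation between genes made the calls. HMOX1, the enzyme that breaks down heme, rose 5.18-fold, from 35.7 ± 8.50 to 185 ± 1.14 RPKM (SD, n = 2). AKR1C1, an NRF2-driven reductase of carbonyl compounds, rose 8.69-fold, from 8.07 ± 1.97 to 70.1 ± 6.56 RPKM (SD, n = 2). COL12A1, a collagen that binds fibril surfaces, fell from 163 ± 12.1 to 30.7 ± 0.299 RPKM (SD, n = 2), and CNN1, the smooth muscle protein calponin, from 158 ± 3.37 to 24.0 ± 1.23 RPKM.

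NRF2 is a transcription factor that switches on antioxidant genes, and of 29 listed targets 20 rose, none fell and 9 did not pass (24 rose when adjusted over the list alone, 16 under median-of-ratios scaling). Their relative median was 0.78 (camera adjusted p = 7.82e-08, adjusted p = 0.454 with an estimated correlation). On GRCh38, HMOX1 lies on chromosome 22 at 35381096 to 35394207 and had a log2 fold change of 2.36 (SE 0.17, limma adjusted p = 1.87e-04). AKR1C1 lies on chromosome 10 at 4963415 to 4983283, with a log2 fold change of 2.99 (SE 0.19, limma adjusted p = 7.44e-05). BLVRB, biliverdin reductase B, rose 3.58-fold and NQO1, a quinone reductase, 2.43-fold (limma adjusted p = 3.62e-04 and 0.00119). The 2 ferritin chains FTH1 and FTL, which store iron, rose 7.02-fold and 4.23-fold, and the metal-binding MT2A rose 5.56-fold. Ferritin, metallothionein and ribosomal protein genes have near-identical copies or pseudogenes, so their read counts are uncertain. Of 28 antioxidant enzymes 20 rose, 1 fell and 7 did not pass (20 and 1 over the list alone, 11 and 1 scaled), with a relative median of 0.51 (camera adjusted p = 2.40e-04, adjusted p = 0.516 with an estimated correlation). Among them the glutathione peroxidases GPX4 and GPX1 rose 3.74-fold and 2.74-fold, and the mitochondrial superoxide dismutase SOD2 2.77-fold (limma adjusted p = 0.00167). Catalase (CAT) had 31.7 ± 6.67 RPKM in control and 28.4 ± 0.0221 in MoS2 1:1 (SD, n = 2, limma adjusted p = 0.604). SQSTM1, the autophagy adaptor p62, rose 4.53-fold to 1001 ± 13.1 RPKM (SD, n = 2).

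Of 40 collagens and other matrix genes 29 fell, 2 rose and 9 did not pass (32 and 3 over the list alone). Their relative median was -1.34 (camera adjusted p = 2.08e-33, adjusted p = 0.271 with an estimated correlation). COL11A1, a cartilage collagen, fell to 0.0325 of its control level, THBS2, a matrix glycoprotein, to 0.193, COL4A1 of basement membranes to 0.216, and COL1A1 to 0.358. COL12A1 lies on chromosome 6 at 75084326 to 75206053, and its log2 fold change was -2.37 (SE 0.15, limma adjusted p = 7.44e-05). Of 23 TGF-beta and myofibroblast genes 12 fell, 2 rose and 9 did not pass (13 and 2 over the list alone), with a relative median of -0.79 (camera adjusted p = 6.75e-12, adjusted p = 0.115 with an estimated correlation). The myofibroblast actin ACTA2 fell to 0.349 and CNN1 (chromosome 19, 11538851 to 11550323) to 0.151 of control. Among 10 smooth muscle and pericyte markers, which share genes with that list, 6 fell, none rose and 4 did not pass, also over the list alone (relative median -1.25, camera adjusted p = 8.74e-10, adjusted p = 0.115 with an estimated correlation). Of 9 chondrogenic genes 7 fell and 2 did not pass, again with the same 7 over the list alone (relative median -1.35, camera adjusted p = 3.77e-11, adjusted p = 0.115 with an estimated correlation). They include the cartilage matrix genes COMP, at 0.326, and HAPLN1, at 0.399 of control. Of 28 targets of the hypoxia factor HIF 9 fell, 1 rose and 18 did not pass, also over the list alone, among them the glucose transporter SLC2A1, at 0.243 of control, and the hormone STC1, at 0.171 (relative median -0.64, camera adjusted p = 1.79e-09, adjusted p = 0.271 with an estimated correlation). Under median-of-ratios scaling 15 HIF targets fell and none rose.

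All 77 cytosolic ribosomal protein genes rose, with the same 77 over the list alone and under median-of-ratios scaling (relative median 0.90, camera adjusted p = 7.61e-20, adjusted p = 0.501 with an estimated correlation). RPS2 rose 2.84-fold. Of 77 mitochondrial ribosomal proteins 63 rose and 14 did not pass (72 rose over the list alone, 40 under median-of-ratios scaling), with a relative median of 0.57 (camera adjusted p = 8.40e-13, adjusted p = 0.501 with an estimated correlation). In the respiratory chain, 33 of 37 complex I subunits rose (35 over the list alone, 21 scaled), and so did 11 of 14 subunits of complexes II and III (13 and 6), 11 of 13 of complex IV (12 and 7) and 16 of 17 of complex V, the ATP synthase (16 and 9). None of them fell. Relative medians were 0.69, 0.43, 0.71 and 0.73, with camera adjusted p = 4.27e-09, 6.37e-04, 2.87e-04 and 2.93e-05, and with adjusted p = 0.501, 0.501, 0.563 and 0.501 with an estimated correlation. NDUFS8 of complex I (chromosome 11, 68030681 to 68036644) rose from 76.5 ± 11.8 to 191 ± 14.4 RPKM (SD, n = 2), UQCRQ of complex III 2.23-fold, COX5B of complex IV 2.32-fold and ATP5G2 of complex V 2.32-fold (limma adjusted p = 0.00119, 0.00213, 0.00141 and 0.00101). Of 30 mitochondrial import genes 21 rose and 9 did not pass (27 over the list alone, 12 scaled), TIMM13 by 2.25-fold (relative median 0.43, camera adjusted p = 9.44e-06, adjusted p = 0.501 with an estimated correlation). Of 31 proteasome subunits 28 rose and 3 did not pass (31 over the list alone, 8 scaled; relative median 0.47, camera adjusted p = 1.44e-06, adjusted p = 0.554 with an estimated correlation). Genes with short coding lengths were higher in general: the shortest 20% of genes, with a median of 555 bases, had a median log2 fold change of 0.59 and the longest 20%, at 3576 bases, one of 0.16. In these classes 45.1% and 11.4% of genes were called higher. Against random lists matched on coding length, GC content and level, the 95% range held the medians of complexes II and III (percentile 78.9), complex IV (93.9), mitochondrial import (97.0) and the mitochondrial unfolded protein response (95.8). Cytosolic and mitochondrial ribosomal proteins, complexes I and V, the proteasome and NRF2 targets lay above that range, and antioxidant enzymes just above it (97.8).

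The regulators of mitochondrial biogenesis did not move as a list. Of 26 listed genes 8 rose, 1 fell and 17 did not pass, with the same counts over the list alone and 2 each way under median-of-ratios scaling (relative median 0.02, camera adjusted p = 0.830, adjusted p = 0.924 with an estimated correlation). TWNK, the helicase of mitochondrial DNA, rose 2.38-fold (limma adjusted p = 0.0106), and TOP1MT, its topoisomerase, 1.95-fold (limma adjusted p = 0.0106, and 0.0835 after scaling). TFAM, which packs mitochondrial DNA, had 7.08 ± 2.76 RPKM in control and 6.14 ± 0.170 in MoS2 1:1 (SD, n = 2, limma adjusted p = 0.700). NRF1, ESRRA, SIRT1 and SIRT3 had log2 fold changes of 0.13, 0.57, 0.43 and 0.30 (limma adjusted p = 0.594, 0.0808, 0.257 and 0.212), and the signs of NRF1 and SIRT3 flipped under median-of-ratios scaling. PPARGC1A and the 13 mitochondrially encoded mRNAs were not analysed here. Of 13 genes of the mitochondrial unfolded protein response 8 rose and 5 did not pass (9 over the list alone, 1 scaled; relative median 0.28, camera adjusted p = 0.0348, adjusted p = 0.479 with an estimated correlation), a call that ended under scaling (camera adjusted p = 0.0883) and without MoS2 1:1 replicate 2 (0.0647).

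Among the 10 highest log2 fold changes of the model were the chemokine CXCL8 (35.8-fold, from 0.610 ± 0.178 to 21.8 ± 0.814 RPKM, SD, n = 2), the bone matrix protein SPP1 (26.9-fold), the differentiation inhibitor ID1 (13.0-fold), the collagenase MMP1 (11.1-fold), the chromatin protein HMGA1 (7.76-fold) and the membrane glycoprotein GPNMB (7.34-fold). The lysosomal protease CTSK rose 6.50-fold. Among the 10 lowest were the adipocyte hormone LEP, from 35.4 ± 3.39 to 0.271 ± 0.383 RPKM, the embryonic myosin MYH3, from 46.6 ± 1.65 to 1.94 ± 0.154, FNDC1, from 182 ± 2.20 to 16.6 ± 0.308, and IGFBP5, a binding protein of insulin-like growth factors, from 139 ± 40.8 to 17.6 ± 0.106 (SD, n = 2). Their limma adjusted p ranged from 3.08e-05 (MYH3 and FNDC1) to 1.87e-04 (IGFBP5). Of 13 genes of osteogenic differentiation 4 rose and 4 fell, and 5 did not pass (5 and 4 over the list alone), with the RANKL decoy receptor TNFRSF11B among those that fell, at 0.239 of control. The relative median of that list was -0.49 (median -0.18 and mean 0.04 on the deposited scale), and its camera test was lower (adjusted p = 0.0183, and 0.501 with an estimated correlation), ending under scaling (camera adjusted p = 0.138), without control replicate 2 (0.0794) and without MoS2 1:1 replicate 1 (0.0906).

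Further lists lay lower against all genes, none past the threshold with an estimated correlation. In endoplasmic reticulum stress 4 of 21 genes fell and 1 rose (2 and 1 over the list alone, and camera adjusted p = 1.21e-05, adjusted p = 0.459 with an estimated correlation). Under median-of-ratios scaling 12 of these genes fell and none rose. Of 19 YAP and TAZ targets 5 fell and 1 rose, also over the list alone (camera adjusted p = 3.13e-05, adjusted p = 0.454 with an estimated correlation). Actin and focal adhesion genes were split, with 6 of 33 lower and 5 higher, also over the list alone, a relative median of -0.31 (-0.01 on the deposited scale), and none higher under scaling (camera adjusted p = 3.01e-04, adjusted p = 0.501 with an estimated correlation). Insulin, IGF and mTOR signalling had 4 of 26 lower and 3 higher (4 and 2 over the list alone; camera adjusted p = 0.00420, adjusted p = 0.501 with an estimated correlation, and 0.0588 without control replicate 2), with a relative median of -0.24 (median 0.06 and mean -0.13 on the deposited scale). In Wnt signalling 4 of 14 fell and 4 rose (5 and 4 over the list alone; camera adjusted p = 0.0259, adjusted p = 0.501 with an estimated correlation, 0.0755 scaled, and not past the threshold without control replicate 2). Of 8 histone mRNAs, which lack a poly(A) tail, 1 fell, also over the list alone (camera adjusted p = 0.0228, adjusted p = 0.501 with an estimated correlation, and not past the threshold without control replicate 1).

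In all, 3359 genes passed in limma, 2885 higher and 474 lower (85.9% higher), and after median-of-ratios scaling 2037 did, 1040 higher and 997 lower. Both scalings called 1040 genes higher and 474 lower, and no call changed sign. At a change of at least 2-fold 932 genes passed, 759 higher and 173 lower. In 68.7% of genes the libraries of the groups did not overlap, where chance gives 33.3% for a single gene. Genes are not independent, and library differences shared by many of them, technical ones included, raise this share. The excess over 33.3% therefore does not measure an effect of the particles. Without MoS2 1:1 replicate 1 the count was 751 and without replicate 2 it was 826, against 5022 without control replicate 1. Of 52 lists tested, 23 passed in camera and 29 did not, and with an estimated correlation none did (lowest adjusted p = 0.115).

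**Figure D1:**
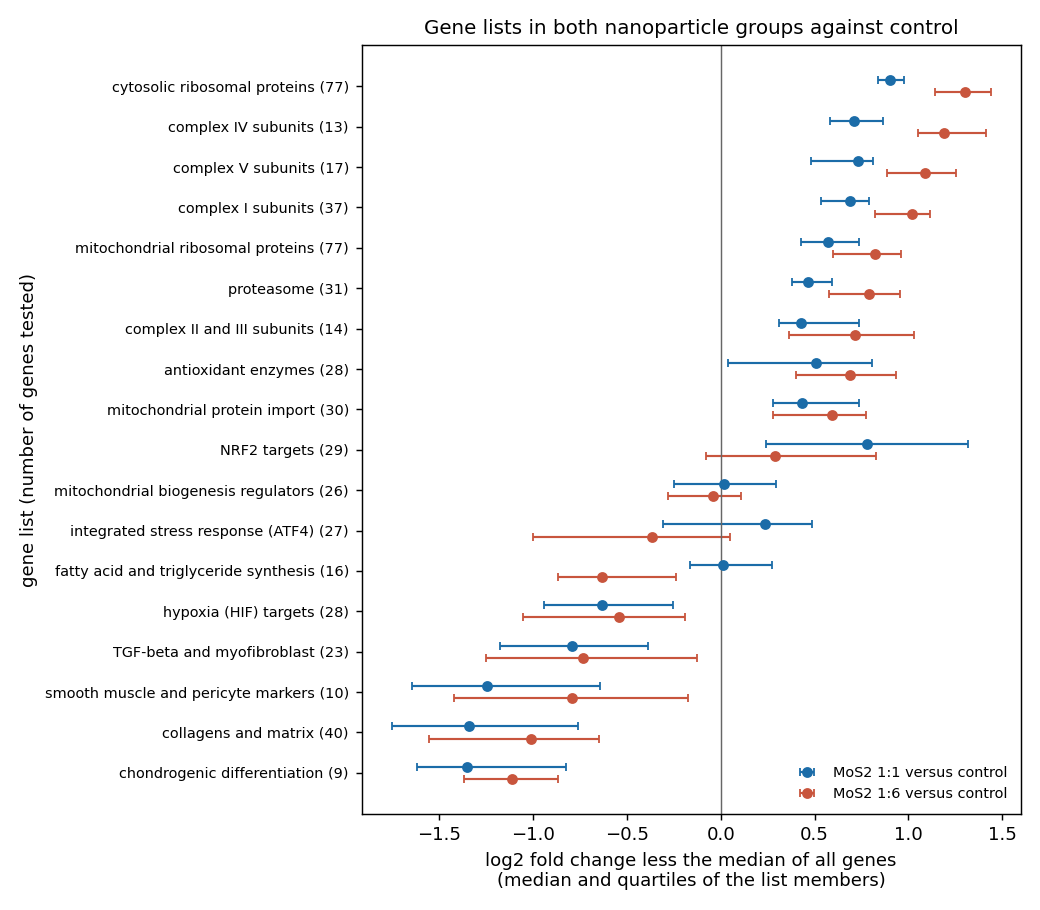
Median log2 fold change of 18 gene lists, less the median of all genes, in MoS2 1:1 (blue) and MoS2 1:6 (red) against control, with bars from the lower to the upper quartile of list members. Ribosomal, respiratory chain and proteasome lists lie above 0 in both, collagens and chondrogenic genes below 0 in both, and regulators of mitochondrial biogenesis at 0.02 and -0.04.

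The comparison of MoS2 1:6 with control asks the same of particles with many vacancies. All 77 cytosolic ribosomal proteins, 35 of 37 complex I subunits and 30 of 31 proteasome subunits rose, while 29 of 40 matrix genes, 10 of 27 genes of the integrated stress response and 5 of 16 of fatty acid and triglyceride synthesis fell. Each of these list calls was lost with an estimated correlation (adjusted p = 0.469). COX5A, a subunit of complex IV, rose 3.01-fold, from 93.3 ± 23.7 to 281 ± 13.1 RPKM (SD, n = 2). FTH1 rose 6.05-fold to 17792 ± 537 RPKM and ID1 9.15-fold to 55.2 ± 6.03 RPKM (SD, n = 2). THBS2 fell from 221 ± 37.6 to 38.1 ± 5.94 RPKM, and SLC7A5, a transporter of large amino acids, from 120 ± 29.3 to 30.2 ± 5.30 RPKM (SD, n = 2).

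All 77 cytosolic ribosomal protein genes rose, also over the list alone and under scaling, RPS2 by 3.01-fold, with a relative median of 1.30 (camera adjusted p = 2.66e-24, adjusted p = 0.469 with an estimated correlation). Of 77 mitochondrial ribosomal proteins 64 rose and 13 did not pass (71 over the list alone, 61 scaled), MRPL11 by 2.80-fold (relative median 0.82, camera adjusted p = 3.44e-14, adjusted p = 0.469 with an estimated correlation). In complex I 35 of 37 subunits rose (37 over the list alone, 32 scaled), in complexes II and III 11 of 14 (12 and 10), in complex IV 12 of 13 (12 and 12) and in complex V 16 of 17 (16 and 15), and none fell. Relative medians were 1.02, 0.72, 1.19 and 1.09, with camera adjusted p = 5.54e-12, 1.41e-04, 2.76e-06 and 6.00e-07, each with adjusted p = 0.469 with an estimated correlation. COX5A (chromosome 15, 74919791 to 74938073) passed with limma adjusted p = 0.00109. COX8A rose 2.59-fold, NDUFA13 2.41-fold, NDUFB2 2.42-fold, UQCRB 3.21-fold and ATP5G1 2.68-fold, with limma adjusted p from 9.39e-04 (COX8A) to 0.00251 (UQCRB). Of 30 import genes 21 rose and 9 did not pass (24 over the list alone), TIMM10 by 2.61-fold (relative median 0.60, camera adjusted p = 4.56e-06, adjusted p = 0.469 with an estimated correlation). Of 31 proteasome subunits 30 rose (30 over the list alone, 25 scaled), PSMB6 by 2.22-fold (relative median 0.79, camera adjusted p = 8.03e-09, adjusted p = 0.469 with an estimated correlation). The trend with coding length was steeper here: the shortest 20% of genes had a median log2 fold change of 0.64 and the longest 20% one of -0.08. In these classes 52.0% and 6.52% of genes were called higher. The range of matched lists held the medians of complexes II and III (percentile 84.8) and mitochondrial import (96.6), while both ribosomal lists, complexes I, IV and V and the proteasome lay above it.

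Regulators of mitochondrial biogenesis again did not move as a list, with 4 of 26 higher, 1 lower and 21 not passing (2 and 1 over the list alone, 2 each way scaled; relative median -0.04, camera adjusted p = 0.894, adjusted p = 0.960 with an estimated correlation). SSBP1, which binds single-stranded mitochondrial DNA, rose 2.99-fold (limma adjusted p = 0.00286), and TFB1M, a mitochondrial rRNA methyltransferase, 2.10-fold (limma adjusted p = 0.0117). TFAM had 5.49 ± 0.872 RPKM in MoS2 1:6 (SD, n = 2, limma adjusted p = 0.398). NRF1, ESRRA, SIRT1 and SIRT3 had log2 fold changes of 0.04, 0.20, -0.12 and 0.29 (limma adjusted p = 0.858, 0.498, 0.753 and 0.214), and NRF1 had the opposite sign, at -0.14, under median-of-ratios scaling.

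Of 29 NRF2 targets 15 rose, 2 fell and 12 did not pass, also over the list alone (relative median 0.29, camera adjusted p = 0.0262, adjusted p = 0.481 with an estimated correlation), a call that ended without MoS2 1:6 replicate 2 (camera adjusted p = 0.0613). The median of NRF2 targets, 0.47, lay inside the range of matched lists, 0.11 to 0.58 (percentile 82.6). FTL rose 2.89-fold, BLVRB 3.30-fold, the redox protein TXN 3.39-fold and NQO1 1.63-fold (limma adjusted p = 0.00113, 6.60e-04, 0.00172 and 0.00813). HMOX1 rose 1.54-fold, from 35.7 ± 8.50 to 55.1 ± 0.226 RPKM (SD, n = 2, limma adjusted p = 0.0225), and did not pass after median-of-ratios scaling (limma adjusted p = 0.115) or without any 1 of the nanoparticle libraries (0.0536 to 0.116). Of 28 antioxidant enzymes 21 rose, 2 fell and 5 did not pass (22 and 2 over the list alone), GPX4 by 3.28-fold and SOD2 by 1.83-fold (relative median 0.69, camera adjusted p = 1.47e-04, adjusted p = 0.470 with an estimated correlation), also inside the matched range, at percentile 91.2. CAT had a log2 fold change of -0.37 and did not pass in limma, and was lower with scaling, at -0.58 (limma adjusted p = 0.0226). Of 10 metallothionein and metal response genes 4 rose, among them MT2A by 4.67-fold and MT1X by 3.66-fold, 3 fell and 3 did not pass (relative median -0.37, camera adjusted p = 0.509, and with MoS2 1:1 4 rose and 2 fell, -0.23 and 0.623).

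Of 40 matrix genes 29 fell, 1 rose and 10 did not pass (30 and 1 over the list alone), with a relative median of -1.01 (camera adjusted p = 6.69e-17, adjusted p = 0.469 with an estimated correlation). THBS2 (chromosome 6, 169215785 to 169253846) stood at 0.173 of control (limma adjusted p = 3.33e-04), and COL11A1, COL12A1 and COL4A1 stood at 0.0754, 0.205 and 0.207 of control. In chondrogenic genes 7 of 9 fell (8 over the list alone), HAPLN1 to 0.495 (relative median -1.11, camera adjusted p = 2.76e-06, adjusted p = 0.411 with an estimated correlation). Of 23 TGF-beta and myofibroblast genes 12 fell, 2 rose and 9 did not pass, also over the list alone, with CNN1 at 0.438 (relative median -0.73, camera adjusted p = 3.47e-05, adjusted p = 0.411 with an estimated correlation). Of 10 smooth muscle markers 5 fell and 5 did not pass (5 fell and 1 rose over the list alone; relative median -0.79, camera adjusted p = 0.00113, adjusted p = 0.469 with an estimated correlation). HIF targets had 13 of 28 lower and 1 higher, also over the list alone, with SLC2A1 at 0.291 and STC1 at 0.137 (relative median -0.54, camera adjusted p = 1.18e-05, adjusted p = 0.469 with an estimated correlation). Of 15 matrix metalloproteinases and their inhibitors 6 fell and 3 rose (9 and 3 over the list alone), the membrane-bound MMP14 to 0.561 (relative median -0.70, camera adjusted p = 0.0110, adjusted p = 0.469 with an estimated correlation). That call on matrix metalloproteinases and inhibitors ended with RPKM rescaled to the same sum (camera adjusted p = 0.0713).

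Of 27 genes of the integrated stress response, which ATF4 drives, 10 fell, 4 rose and 13 did not pass (10 and 5 over the list alone; relative median -0.37, camera adjusted p = 0.0132, adjusted p = 0.469 with an estimated correlation). The amino acid transporters SLC7A5 (chromosome 16, 87830023 to 87869507) and SLC7A1 stood at 0.252 and 0.237 of control, while the stress protein NUPR1 rose 2.15-fold and the phosphatase subunit PPP1R15A 1.96-fold (limma adjusted p = 9.39e-04, 0.00222, 0.00129 and 0.00206). Of 16 fatty acid and triglyceride synthesis genes 5 fell, 1 rose and 10 did not pass (7 and 1 over the list alone), including the desaturases FADS2, at 0.341, and SCD, at 0.436, and the elongase ELOVL5, at 0.425 (relative median -0.63, camera adjusted p = 0.00130, adjusted p = 0.469 with an estimated correlation). Of 20 mesenchymal stromal cell markers 8 fell, 5 rose and 7 did not pass (8 and 6 over the list alone; relative median -0.39, camera adjusted p = 0.0262, adjusted p = 0.469 with an estimated correlation, and 0.0589 without control replicate 2). The growth factor receptors PDGFRB and PDGFRA stood at 0.302 and 0.412, and the adhesion proteins MCAM and ALCAM at 0.327 and 0.368 of control.

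Further lists lay lower against all genes. Of 33 actin and focal adhesion genes 13 fell and 2 rose (14 and 3 over the list alone), the integrin ITGAV to 0.175 and vinculin (VCL) to 0.352, while profilin (PFN1) rose 2.25-fold (camera adjusted p = 5.32e-04, adjusted p = 0.469 with an estimated correlation). Of 19 YAP and TAZ targets 8 fell and 1 rose, also over the list alone, CRIM1 to 0.277 (camera adjusted p = 4.20e-04, adjusted p = 0.469 with an estimated correlation). Of 26 genes of insulin, IGF and mTOR signalling 8 fell and 2 rose, also over the list alone, IGFBP5 to 0.152 (camera adjusted p = 0.0110, adjusted p = 0.469 with an estimated correlation, and 0.0571 without control replicate 2), with a median inside the range of matched lists (percentile 3.99). Of 21 genes of endoplasmic reticulum stress and unfolded protein response 6 fell and 3 rose (7 and 3 over the list alone; camera adjusted p = 0.0262, adjusted p = 0.469 with an estimated correlation, 0.0885 without control replicate 1 and 0.0965 without MoS2 1:6 replicate 1). In Wnt signalling 5 of 14 fell and 3 rose (5 and 4 over the list alone; camera adjusted p = 0.0446, adjusted p = 0.469 with an estimated correlation), a call that ended under scaling (camera adjusted p = 0.0782), without control replicate 2 (0.158) and without MoS2 1:6 replicate 2 (0.0677). Further low genes were LEP, at 0.0687 of control, the potassium channel subunit KCNE4, at 0.141, the hyaluronan-binding CEMIP, at 0.158, FNDC1, at 0.162, and MYH3, at 0.157, and the fatty acid carrier FABP5 rose 6.06-fold.

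In all, 4125 genes passed in limma, 2845 higher and 1280 lower (69.0% higher), and after median-of-ratios scaling 4066 did, 2046 higher and 2020 lower. Both of these scalings called 2045 higher and 1280 lower, and no call changed sign. With RPKM rescaled to the same sum the balance reversed, with 1042 higher and 3433 lower. At 2-fold 1399 genes passed, 996 higher and 403 lower. The libraries of both groups stood apart in 68.8% of genes, where chance gives 33.3% for a single gene, with the same limit as for MoS2 1:1. Without MoS2 1:6 replicate 1 the count was 2341 and without replicate 2 it was 1367. Of 52 lists 24 passed in camera, and with an estimated correlation none did.

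The direct comparison of MoS2 1:6 with MoS2 1:1 asks what the difference in vacancies changed. The NRF2, ATF4 and fatty acid synthesis lists lay lower with the high-vacancy particles, with 6 of 29, 8 of 27 and 3 of 16 genes past the threshold, and 3 of 10 smooth muscle markers were higher. These list calls were lost with an estimated correlation (adjusted p = 0.532, 0.283, 0.532 and 0.532). HMOX1 fell from 185 ± 1.14 to 55.1 ± 0.226 RPKM (SD, n = 2), AKR1C1 from 70.1 ± 6.56 to 18.4 ± 1.39, and the pseudokinase TRIB3, an ATF4 target, from 60.2 ± 4.79 to 19.7 ± 2.52. ACTA2 rose 2.99-fold, from 185 ± 3.87 to 553 ± 14.6 RPKM (SD, n = 2), beside 530 ± 77.8 in control. These calls rest on every nanoparticle library: with any 1 of the 4 left out, limma called 0 genes, with 1075 to 2128 at an unadjusted p under 0.05.

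Of 29 NRF2 targets 6 fell, none rose and 23 did not pass (20 fell over the list alone), with a relative median of -0.42 (camera adjusted p = 5.38e-07, adjusted p = 0.532 with an estimated correlation). HMOX1 and AKR1C1 had log2 fold changes of -1.73 (SE 0.17) and -1.88 (SE 0.19), both with limma adjusted p = 0.00685. AKR1B10, another reductase, stood at 0.225 and the thioredoxin reductase TXNRD1 at 0.530 of the MoS2 1:1 level (limma adjusted p = 0.0241 and 0.0431). NQO1 and SOD2 had log2 fold changes of -0.57 and -0.57 and did not pass (limma adjusted p = 0.0839 and 0.127), nor did CAT (0.493). SQSTM1 fell to 0.469 (limma adjusted p = 0.0186). Of 27 integrated stress response genes 8 fell, none rose and 19 did not pass (17 fell over the list alone; relative median -0.52, camera adjusted p = 3.05e-09, adjusted p = 0.283 with an estimated correlation). TRIB3 (chromosome 20, 380760 to 397559) had a log2 fold change of -1.57 (SE 0.16, limma adjusted p = 0.00685), and the growth factor GDF15, the transcription factor ATF3 and SLC7A5 stood at 0.424, 0.363 and 0.315 of MoS2 1:1 (limma adjusted p = 0.0122, 0.0135 and 0.0160). SESN2, a leucine sensor, stood at 0.332.

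Of 16 fatty acid and triglyceride synthesis genes 3 fell, none rose and 13 did not pass (10 fell over the list alone; relative median -0.46, camera adjusted p = 5.54e-06, adjusted p = 0.532 with an estimated correlation). They were SCD, at 0.222, FADS1, at 0.331, and the fatty acid synthase FASN, at 0.445, which did not pass after scaling (limma adjusted p = 0.0573). G0S2, an inhibitor of fat breakdown, stood at 0.264. Of 26 p53 targets 3 fell (13 fell and 1 rose over the list alone; camera adjusted p = 0.00636, adjusted p = 0.532 with an estimated correlation, and 0.0812 without MoS2 1:6 replicate 1), GDF15, the cell cycle inhibitor CDKN1A, at 0.532, and the death receptor TNFRSF10B, at 0.509. Of 15 metalloproteinases and inhibitors MMP1 fell, at 0.411 (10 fell over the list alone; camera adjusted p = 1.47e-04, adjusted p = 0.532 with an estimated correlation). Of 25 immediate early genes ATF3 fell (5 over the list alone; camera adjusted p = 0.00468, adjusted p = 0.640 with an estimated correlation, 0.0515 without MoS2 1:1 replicate 2 and 0.380 without MoS2 1:6 replicate 1). The chemokines CXCL8 and CXCL3 stood at 0.178 and 0.0850, SPP1 at 0.335, and the iron and zinc importers TFRC and SLC39A14 at 0.404 and 0.345 of MoS2 1:1.

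Of 10 smooth muscle and pericyte markers 3 rose, none fell and 7 did not pass (4 rose and 3 fell over the list alone; relative median 0.18, camera adjusted p = 0.0150, adjusted p = 0.532 with an estimated correlation, 0.0860 without control replicate 1, 0.0848 without control replicate 2 and 0.0886 with only the 4 libraries compared). They were ACTA2, CNN1, at 2.90-fold, and SYNPO2, at 2.80-fold. ACTG2, a smooth muscle actin (chromosome 2, 73893008 to 73919865), rose 3.88-fold with a log2 fold change of 1.84 (SE 0.14, limma adjusted p = 0.00685). CSRP2 rose 3.21-fold, PPP1R14A 2.92-fold, MYH3 3.79-fold and the calcium-binding S100A4 2.78-fold. Ribosomal and respiratory lists lay higher than all genes with no member passing, also over the list alone: cytosolic ribosomal proteins (relative median 0.40, camera adjusted p = 1.42e-11, adjusted p = 0.694 with an estimated correlation) and complexes I, IV and V (0.28, 0.50 and 0.42, camera adjusted p = 7.56e-06, 6.19e-06 and 3.12e-05, adjusted p = 0.617 for each with an estimated correlation). The proteasome (0.28, camera adjusted p = 7.55e-05, adjusted p = 0.753 with an estimated correlation) and mitochondrial ribosomal proteins (0.19, camera adjusted p = 0.00256, adjusted p = 0.802 with an estimated correlation, and just not past the threshold without MoS2 1:6 replicate 2) did the same. Of these, the range of matched lists held the medians of complex I (0.16 against 0.10, percentile 84.6) and mitochondrial ribosomal proteins (0.0771 against 0.0489, percentile 78.1). Under quantile normalization the cytosolic ribosomal call ended (camera adjusted p = 0.672). Epithelial markers (0.60, camera adjusted p = 6.19e-04, adjusted p = 0.532 with an estimated correlation), G2 and M phase genes (0.41, camera adjusted p = 0.00134, adjusted p = 0.532 with an estimated correlation) and histone mRNAs (0.57, camera adjusted p = 0.00256, adjusted p = 0.532 with an estimated correlation) also lay higher. Complexes II and III did not pass (camera adjusted p = 0.0550), nor did the regulators of mitochondrial biogenesis, with no member passing (camera adjusted p = 0.725). SIRT1, SIRT3, NRF1, TFAM and ESRRA had log2 fold changes of -0.56, -0.01, -0.08, -0.14 and -0.37 (limma adjusted p = 0.272, 0.979, 0.807, 0.765 and 0.356), with the signs of SIRT3 and NRF1 flipped under median-of-ratios scaling.

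In all, 128 genes passed in limma between the nanoparticle groups, 27 higher and 101 lower in MoS2 1:6, and after median-of-ratios scaling 179 did, 94 higher and 85 lower. Both scalings called 27 higher and 80 lower. At 2-fold 93 passed, 19 higher and 74 lower, and 2502 genes had an unadjusted p under 0.05. These counts use 1 variance per gene over all groups, and replicates spread more in the controls (SD 0.40) than in MoS2 1:1 (0.21) or MoS2 1:6 (0.30). With only the 4 nanoparticle libraries fitted 2243 genes passed, so the count of 128 depends on the control libraries and does not measure how far the particles differ. The libraries stood apart in 64.8% of genes, where chance gives 33.3% for a single gene, and differences shared by many genes raise this share here too. Without control replicate 1 the count was 2268 and without replicate 2 it was 2259. Of 52 lists 20 passed in camera, and with an estimated correlation none did.

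**Figure D2:**
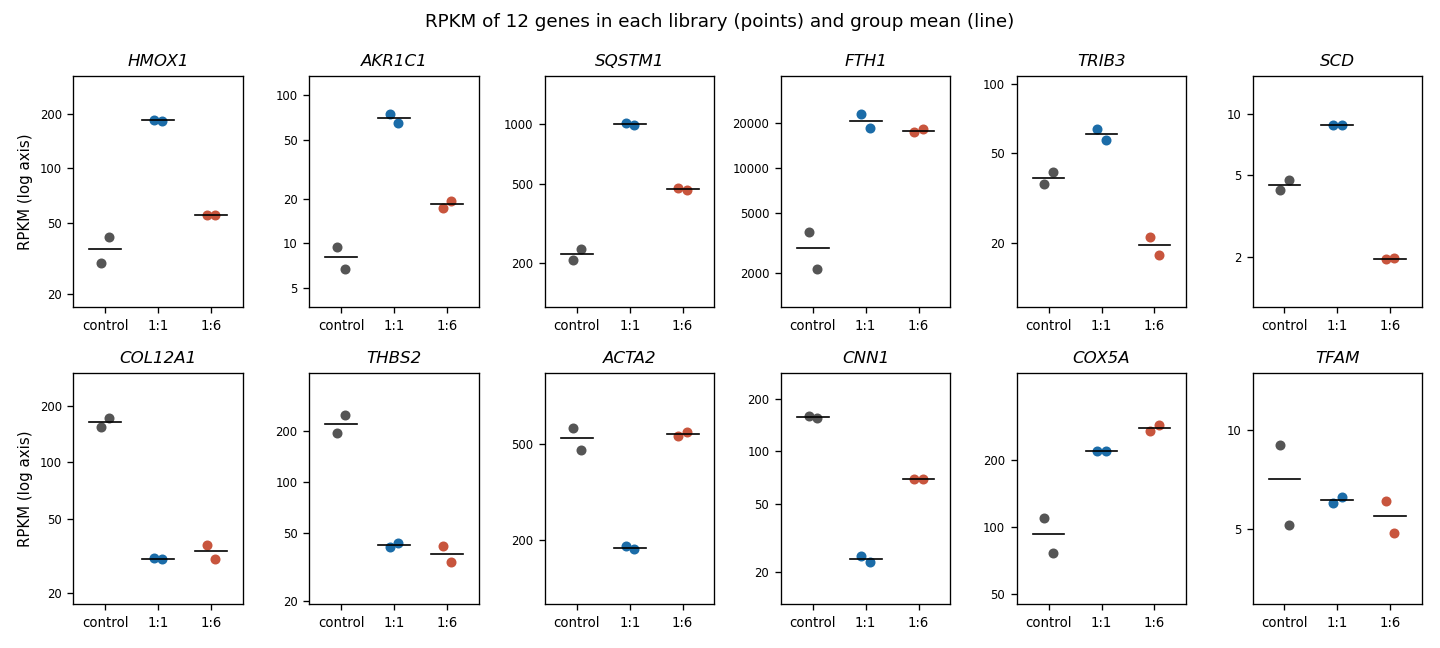
RPKM (log axes) of 12 genes in the 6 libraries, as points, with a line at each group mean. HMOX1, AKR1C1 and SQSTM1 are highest in MoS2 1:1, COL12A1 and THBS2 are low in both nanoparticle groups, ACTA2 is low in MoS2 1:1 alone, COX5A is higher in both nanoparticle groups, and the TFAM values of the groups overlap.

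The responses to both particles, each against the same control libraries, were compared across genes, which are not independent replicates. Fold changes had a Pearson r of 0.813 and a Spearman rho of 0.811. In 100 simulations unchanged groups, with the same spread per gene in controls and nanoparticle groups, gave a mean r of 0.500, at most 0.524. An r near 0.500 follows from that equal spread. Measured replicates spread more in the controls (SD 0.40) than in MoS2 1:1 (0.21) or MoS2 1:6 (0.30). A larger control spread raises r, the covariance and the share of equal signs of unchanged groups, so the simulated values are too low a benchmark. The covariance was 0.267, against 0.0211 in the simulations with equal spread, a difference of 0.246. In 78.8% of genes the sign was the same, against 66.7% in the simulations with equal spread. In both comparisons 2083 genes were higher, where independent lists would share 737, and 375 were lower, where independent lists would share 54.5. After median-of-ratios scaling these overlaps were 883 against 191 and 783 against 181. Error in the shared controls also makes such lists overlap, so independent lists do not give the overlap of unchanged groups. With a control library of its own for each group, a test chosen after seeing the data, r was 0.509 with MoS2 1:1 against control replicate 1 and 0.756 the other way round, and the covariance 0.194 and 0.259. No control error is shared there, so the simulated 0.500 is not the benchmark for these values. Independent error alone would give no correlation, while a handling difference shared by both controls would still raise it.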

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

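The tests in this part were planned before their results were seen. The effects of the 2 particles differed, by the direct test of MoS2 1:6 against MoS2 1:1 in limma, in 128 genes. That fit holds the spread of the controls, and with only the 4 nanoparticle libraries fitted the count was 2243. Of the 128, 3 genes were called on the deposited RPKM in opposite directions against control: SCD, which desaturates fatty acids, TRIB3, and the cell surface proteoglycan SDC1, chosen after its values were seen. SCD had 4.49 ± 0.383 RPKM in control, 8.85 ± 0.00606 in MoS2 1:1 and 1.96 ± 0.00820 in MoS2 1:6, TRIB3 38.7 ± 3.27, 60.2 ± 4.79 and 19.7 ± 2.52, and SDC1 2.98 ± 0.0852, 5.12 ± 0.767 and 1.71 ± 0.169 (SD, n = 2). Their limma adjusted p for the difference was 0.00685, 0.00685 and 0.0393. After median-of-ratios scaling the rise in MoS2 1:1 no longer passed (limma adjusted p = 0.0757, 0.292 and 0.270). With that scaling 1 other gene was called in opposite directions, the small heat shock protein CRYAB, chosen after its values were seen, at a log2 fold change of -0.55 in MoS2 1:1 and 0.44 in MoS2 1:6 (limma adjusted p = 0.0216 and 0.0319), against -0.20 and 0.65 (0.352 and 0.0117) on the deposited RPKM. With any nanoparticle library left out limma called 0 genes, with 1075 to 2128 genes at an unadjusted p under 0.05.

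Of NRF2 targets 6 of 29 and of ATF4 targets 8 of 27 were lower in MoS2 1:6 than in MoS2 1:1 and none higher, with a median log2 fold change of -0.55 over the 55 genes of both lists. Random lists matched on coding length, GC content and level had a median of -0.04 (95% from -0.15 to 0.05), and the targets lay at percentile 0 of them, which argues against a trend shared by all genes. With all libraries thinned to 9388026 reads, the higher adjusted camera p of both lists was 5.85e-07, against fewer reads in MoS2 1:6, though with an estimated correlation neither list passed at full depth (adjusted p = 0.532 and 0.283). With 1 nanoparticle library left out, the median less that of all genes came no closer to 0 than -0.36, against a single library out of place. Histone mRNAs, which lack a poly(A) tail, and epithelial markers also lay higher in MoS2 1:6 (relative medians 0.57 and 0.60, camera adjusted p = 0.00256 and 6.19e-04, adjusted p = 0.532 for each with an estimated correlation), and differences in library handling or cell content between the groups stay open, with no biological explanation tested.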

How the results depend on the processing

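Chosen after seeing the data were voom on recovered reads, voom with median-of-ratios totals, totals without the 20 most abundant genes, median-of-ratios scaling with a replicate block, and separate controls for the correlation of the responses. Where a value moved, the cause was not tested. Leaving out a library leaves 1 in its group, which is assumed to vary like the others. The setting without a filter removed no tested gene and so says nothing, and groups of 2 allow no count of other splits. Camera sets a list against all other genes, while fry tests it against no change, and mixed fry without a direction, so counts by fry are not of lists shifted against other genes. With an estimated correlation camera has only 3 degrees of freedom, so its lost calls do not measure the effect of correlation alone. The labels do not say whether the replicate numbers pair the libraries. Correlations of replicate differences ran from -0.23 to 0.13, which with 2 libraries per group cannot decide it.

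MoS2 1:1 against control, as changed, higher and lower genes: median-of-ratios 2037, 1040, 997; quantile 1904, 938, 966; equal sums 1970, 941, 1029; median-of-ratios with block 1772, 904, 868; 2-fold 932, 759, 173. Voom with median-of-ratios totals gave 1156 higher and 1256 lower, and totals without the top 20 genes 1636 higher. With 1 library left out the ranges were 751 to 5022 changed, 615 to 4397 higher and 136 to 625 lower: 751 and 826 without MoS2 1:1 replicates 1 and 2, and 5022 without control replicate 1. By camera 0 lists shifted with an estimated correlation and 21 to 26 with a library left out. Fry called 35 lists by directional and 51 by mixed p.

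MoS2 1:6 against control: 2-fold 1399, 996 and 403; quantile 1822 higher; equal sums 1042 higher and 3433 lower; median-of-ratios 2020 lower; voom with median-of-ratios totals 2109 lower. With 1 library left out 1367 to 5512 changed, 970 to 3988 higher and 397 to 1524 lower, with 2341 and 1367 without MoS2 1:6 replicates 1 and 2. By camera 0 lists shifted with an estimated correlation and 21 to 24 with a library left out. Fry called 51 lists by mixed p.

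MoS2 1:6 against MoS2 1:1: pseudocount 0.1 58, 15 and 43; pseudocount 0.01 50, 13 and 37; median-of-ratios 94 higher; quantile 52 higher and 41 lower; equal sums 882, 63 and 819; only the 4 libraries 2243, 678 and 1565; no variance trend 82, with 14 higher; block 22, 7 and 15; 2-fold 93, 19 and 74; voom 392, 54 and 338; voom with median-of-ratios totals 433, 200 and 233; median-of-ratios with block 53, with 20 lower. With 1 library left out 0 to 2268 changed, 0 to 685 higher and 0 to 1591 lower: limma called 0 without any 1 nanoparticle library (unadjusted 1075, 1273, 2128 and 1239) and 2268 and 2259 without a control. By camera 0 lists shifted with an estimated correlation and 14 to 21 with a library left out. Fry called 12 lists by directional and 39 by mixed p. The correlation of the responses was 0.776 to 0.871 with a library left out, and 0.509 and 0.756 with separate controls.

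Signs flipped in genes that were not called. Against control in MoS2 1:1, SIRT3 and NRF1 were -0.0158 and -0.18 with median-of-ratios scaling, with and without block, -0.0159 and -0.19 with voom and median-of-ratios totals, and -0.0390 and -0.20 with equal sums; NRF1 was -0.10 by quantile and -0.0381 without the top 20. In MoS2 1:6, NRF1 was -0.14 by median-of-ratios, with and without block, -0.15 by voom with these totals, -0.40 by equal sums and -0.10 without the top 20, and SIRT3 and ESRRA were -0.17 and -0.27 by equal sums. Between the particles, NRF1 was 0.0370 by median-of-ratios, with and without block, 0.0397 by voom with these totals and 0.10 by quantile, SIRT3 0.12, 0.12, 0.15 and, without the top 20, 0.00748, and TFAM 0.0486 by quantile. With 1 library left out, CAT ranged from -0.35 to 0.0721 and TFAM from -0.49 to 0.22 in MoS2 1:1, and in MoS2 1:6 TFAM from -0.64 to 0.0747, NRF1 from -0.0201 to 0.11, SIRT1 from -0.45 to 0.21 and ESRRA from -0.11 to 0.51. SIRT3 ranged from -0.0778 to 0.0559 between the particles. The flips came without control replicate 1 (CAT, TFAM, NRF1 and SIRT1, the last at 0.14), MoS2 1:6 replicate 1 (ESRRA), MoS2 1:6 replicate 2 (SIRT1) and MoS2 1:1 replicate 2 (SIRT3).

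Of called genes named here none changed sign. Over the other settings 709 of 733 calls held for MoS2 1:1, 835 of 854 for MoS2 1:6 and 434 of 493 between them, and with a library left out 280 of 294, 326 of 342 and 66 of 198. Shifted lists kept their direction in each setting of the preset camera test in which they were tested (21, or 20 for G2 and M phase genes), and 18 of 23, 18 of 24 and 11 of 20 stayed past the threshold in all. Beyond losses given elsewhere, calls ended for NRF2 targets in MoS2 1:6 with quantile normalization (camera adjusted p = 0.144) and a minimum RPKM of 5 (0.116), for insulin, IGF and mTOR signalling at that minimum (0.0680 in MoS2 1:1, 0.0880 in MoS2 1:6), and for histone mRNAs in MoS2 1:1 with voom and median-of-ratios totals. Wnt signalling in both, and osteogenic differentiation and the mitochondrial unfolded protein response in MoS2 1:1, ended under several scalings. Between the particles, quantile normalization ended the calls of collagens and matrix (0.979) and of mitochondrial ribosomal proteins (0.0560).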

Other observations

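The 2 tests on the surplus of higher genes were chosen after the result was seen, and the others in this part before. Cells with MoS2 1:1 had 14 of 27 integrated stress response genes higher and 1 lower (relative median 0.24, camera adjusted p = 0.251). Mitochondrial fusion and fission had 8 of 20 higher and none lower (0.17, camera adjusted p = 0.0539), and with MoS2 1:6 8 higher and 1 lower (0.23, camera adjusted p = 0.149). The TCA cycle had 10 of 29 higher and 1 lower with MoS2 1:1, and 10 higher and 2 lower with MoS2 1:6 (camera adjusted p = 0.374 and 0.197). Glycolysis was split, 5 of 23 each way with MoS2 1:1 and 7 higher and 6 lower with MoS2 1:6 (camera adjusted p = 0.0872 and 0.297). Of 33 lysosome genes 13 rose with MoS2 1:1 and none fell (camera adjusted p = 0.425), and between the particles 2 were lower in MoS2 1:6 (camera adjusted p = 0.0303, adjusted p = 0.617 with an estimated correlation), inside the range of matched lists (percentile 3.95). The lysosome call ended with median-of-ratios scaling (camera adjusted p = 0.0902), with voom and median-of-ratios totals (0.0599), without MoS2 1:1 replicate 2 (0.254) and without MoS2 1:6 replicate 1 (0.242).

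Between the particles, collagens and matrix lay higher in MoS2 1:6 (relative median 0.16, camera adjusted p = 0.0108, adjusted p = 0.753 with an estimated correlation), mesenchymal stromal cell markers lower (-0.20, camera adjusted p = 0.0351, adjusted p = 0.532 with an estimated correlation) and adipogenic differentiation higher (0.16, camera adjusted p = 0.0470, adjusted p = 0.617 with an estimated correlation, inside the range of matched lists at percentile 94.0). Each of these calls ended without MoS2 1:6 replicate 1, among other settings. Molybdenum cofactor and molybdoenzyme genes, 10 in the table, had 2 higher with MoS2 1:1 and 1 each way with MoS2 1:6 (camera adjusted p = 0.755 and 0.991). Of markers of other cell types, 1 of 12 endothelial, 4 of 13 neural and glial, 5 of 20 hematopoietic and macrophage, 0 of 10 erythroid and 8 of 14 epithelial genes were in the table. Epithelial markers had 2 genes higher and 1 lower with MoS2 1:1 and 4 higher and 1 lower with MoS2 1:6 (camera adjusted p = 0.456 and 0.297). Between the particles no epithelial gene passed over all genes, 2 of 8 were higher over the list alone and 2 under median-of-ratios scaling, and the median of the list, given in the report, lay at percentile 100 of matched lists. Whether other cells contributed to them was not tested.

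Of respiratory chain and ATP synthase subunits, 33 of 37 in complex I, 11 of 14 in II and III, 11 of 13 in IV and 16 of 17 in V were higher with MoS2 1:1 (21, 6, 7 and 9 with median-of-ratios scaling) and 35, 11, 12 and 16 with MoS2 1:6, with calls lost with an estimated correlation (adjusted p = 0.469 to 0.563). Over all 81 the median log2 fold change was 0.99 with MoS2 1:1 and 1.23 with MoS2 1:6, where matched lists gave 0.70 (95% from 0.56 to 0.81) and 0.81 (0.63 to 0.97), so the subunits lay at percentile 100 in both and exceeded the matched lists by 0.29 and 0.42, against a shared trend as the whole cause. The matched lists still carry most of the rise, and by complex II and III lay inside the matched range in both comparisons (percentiles 78.9 and 84.8) and IV with MoS2 1:1 (93.9), so for these a shared trend stays open. With 1 control left out the median less that of all genes was at least 0.46 and 0.88. With all libraries, matched lists also lay above all genes (0.70 against 0.30, and 0.81 against 0.18), so these values do not bear on the excess over matched lists. The excess between the 2 controls was 33.0% and 23.1% of those against control, against the difference between the controls as the whole cause. For complexes I and V in both groups, and IV with MoS2 1:6, a trend within the matching classes and handling differences between control and nanoparticle libraries stay open. No biological explanation was tested.

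On the deposited RPKM more genes were higher than lower in both nanoparticle groups. Other scalings gave near even counts, 1040 higher and 997 lower with MoS2 1:1 and 2046 and 2020 with MoS2 1:6 by median-of-ratios, or with equal sums the reverse, 1042 higher and 3433 lower with MoS2 1:6. Median-of-ratios scaling removes the median shift of all genes by design, so its near even counts do not tell where the surplus came from. Without the 20 most abundant genes in the totals, 45.8% of the median shift was left with MoS2 1:1 and 20.6% with MoS2 1:6, and 1636 genes were higher and 662 lower with MoS2 1:1 and 2086 and 1801 with MoS2 1:6, so abundant genes taking more of the control reads could explain part of the surplus. Fewer reads in the controls are argued against, since the smaller control library held 1.21 times the mean reads of the nanoparticle libraries. What lowered the share of matrix transcripts was not tested.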
